A study of Candida albicans SC5314 with 6 samples.

How the data were processed

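RNA-seq was performed on 6 samples of Candida albicans SC5314, which the labels place by carbon source in 3 groups of 2 libraries. Per the labels' protocols and the series' design text, total RNA was extracted from anaerobic cultures with a yeast RNA kit, and Illumina libraries were sequenced from both ends by a company. The submitters' processing notes name Trimmomatic (read trimming), STAR 2.7.0a (alignment) and HTSeq 0.11.1 (counting); their parameters, the strand setting, the genome build, the annotation and the way messenger RNA was selected are not given in the sources used here.

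The deposited values are raw read counts, with 1 whole number per gene and library and no normalization by the authors, as the values themselves show. Each file lists 6194 gene identifiers of the orf19 series and 5 closing rows that name no gene. Of these rows, 4 (no feature, ambiguous, low quality and not aligned) are 0 in all 6 libraries. Why they are 0 is not given in the sources used here, so reads that were assigned to no gene are unknown and the listed reads are not the full depth of a library. Of the listed reads, the row for non-unique alignments amounted to 0.948% to 1.91%. Rows that name no gene were left out of library sizes and tests. By the default of HTSeq, alignments in that row are counted for no gene; whether the default was used is not given. Values of genes with near-identical copies are therefore uncertain. It is unknown whether counting used strand, so overlapping and antisense genes cannot be told apart.

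Totals over genes ranged from 15574171 to 20237883 reads per library. At these depths, 3 reads (the limit that a count of 0 allows) correspond to 0.148 to 0.193 CPM (counts scaled to a fixed library total) before TMM scaling. Such limits and the intervals printed for ratios of counts (95%, exact Clopper-Pearson intervals of the share of reads) cover counting error only, and the reads are not counted as unique molecules.

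The files identify genes by orf19 identifiers and do not pair them with names. The RefSeq gene table used here (6263 genes of assembly ASM18296v3) carries other locus tags, and 0 of the 6194 identifiers were found in it. Gene symbols are therefore not given. The 24 gene lists that had been written by symbol before the data were examined (metabolic pathways, transporters, proteases, adhesins, cell states, ribosome and stress genes) could be matched to no identifier. The planned gene list tests, with their alternatives, were not run. The rule for named genes, also fixed before the data were examined, asked for adjusted p below 0.05, libraries of the 2 groups that do not overlap, an average log2 CPM of at least 4, and a standard symbol. Because no identifier has a symbol here, that rule names no gene. With the symbol requirement dropped after the data were seen, the identifier with the largest rise and the one with the largest fall were taken from mucin against base and from glucose against base. No other gene is listed by identifier, including members of counts of 5 or fewer.

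Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 5987 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model (glmQLFit with legacy set to false, glmQLFTest) was fitted to all 6 libraries with 1 mean per group, so that the spread was shared over groups and rested on 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived as the absolute log2 fold change divided by the square root of the F statistic. Where single genes are described, values are TMM-scaled CPM as mean ± SD of 2 libraries. Replicate numbers were assigned in accession order and pair no libraries.

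The fit was tested on simulated data, in which 200 genes of the mucin libraries were changed against the base libraries at the observed depths and dispersions. All 6 libraries were drawn from the pooled base counts, so glucose had the composition of base. The scaling of libraries that differ in composition was therefore not tested. In that mucin against base simulation, which ran on 5859 genes, the fit recovered 8.00% of genes changed 1.25-fold, 43.8% of genes changed 1.5-fold, 84.0% of genes changed 2-fold and 100% of genes changed 4-fold. Of its 120 calls, 5 were genes that had not been changed. The adjusted threshold depends on how many genes change. The real comparison had 1474 calls, so the recovered shares need not hold for it.

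Alternatives were DESeq2 size factors, library size only and upper-quartile scaling; DESeq2 1.42.0 and limma-voom (limma 3.58.1) as tests; no low-count filter, or CPM of at least 10 in at least 2 libraries; fits to only the 4 libraries compared; robust and legacy fits; a test against a 2-fold change (glmTreat); removal of the 20 most abundant genes; and each library left out in turn. Thinning all libraries to the smallest total, the alternatives for the groups of genes by position of mucin, and the scalings of the split by expression level were added after seeing the data. The comparisons of mucin with base and of glucose with base share the base libraries. For their overlap, 50 data sets with unchanged groups were therefore simulated. All 6 libraries, base included, were drawn anew from the pooled base counts, and both comparisons shared the drawn base libraries. The deviations of the real base libraries are not carried in them. Exact permutation tests of single values were not used, since 2 libraries against 2 allow no two-sided p below 0.333.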

Results

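RNA-seq was used to profile Candida albicans SC5314, the reference strain of a yeast that lives as a commensal on human mucosal surfaces and can cause infection. Cells (800 µL of a washed suspension into 20 mL of medium) were incubated without oxygen at 37 °C for 24 h in yeast nitrogen base, a defined medium that supplies nitrogen, vitamins and salts. The medium was given alone (base), with glucose, or with porcine stomach mucin, the heavily glycosylated protein that forms the scaffold of gastric mucus. Each medium had 2 libraries. The labels do not say whether these came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The reads counted in genes numbered 19108512 and 20150432 for base, 17531368 and 20237883 for glucose, and 17591751 and 15574171 for mucin. Of the 6194 listed genes, 6068 to 6108 had at least 1 read in a given library.

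Cells in base medium and cells with mucin concentrated their transcripts in few genes, whereas cells with glucose spread them over many. The 100 most abundant genes of each library took 54.8% ± 0.273 of the reads in base (SD, n = 2), 50.2% ± 0.941 with mucin (n = 2) and 31.1% ± 1.37 with glucose (n = 2). A share of 50% of the reads came from 70 and 73 genes in the base libraries, from 94 and 104 genes in the mucin libraries, and from 340 and 417 genes in the glucose libraries. Of the 100 genes with the highest mean share in base medium, 89 were also among the 100 highest with mucin, and 23 were among the 100 highest with glucose. These 100 base genes held 49.8% ± 1.01 of the reads with mucin and 12.8% ± 0.360 with glucose (SD, n = 2 each).

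**Figure D1:**
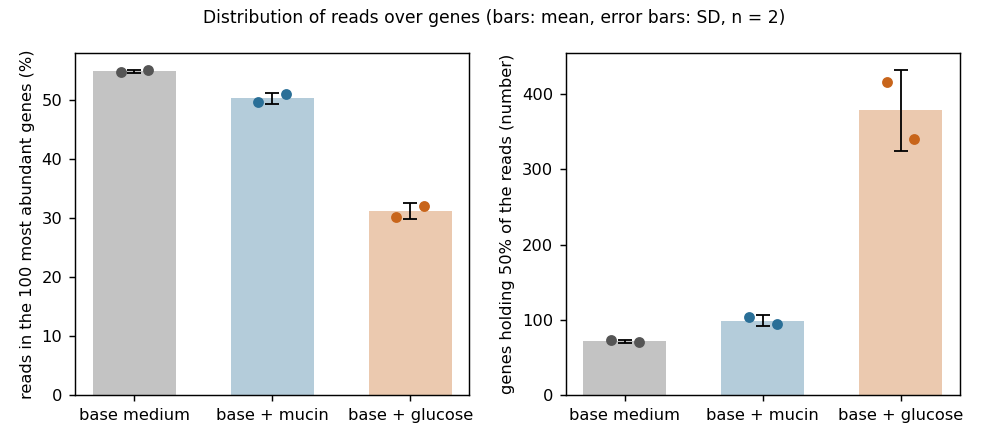
Left, percent of reads in the 100 most abundant genes of each library; right, number of genes that together hold 50% of the reads. Points are libraries, bars are group means and error bars are SD (n = 2); glucose libraries need 340 and 417 genes to reach 50%, against 70 to 104 genes in the other libraries.

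The libraries grouped by medium. Across the 5987 tested genes, the log2 CPM of the paired libraries within a medium correlated at r = 0.989 for base, 0.993 for glucose and 0.987 for mucin. These correlations are across genes, which are not independent replicates. Base and mucin libraries correlated at 0.973 to 0.977, base and glucose libraries at 0.659 to 0.668, and mucin and glucose libraries at 0.685 to 0.693. The median absolute difference between libraries was 0.138 to 0.177 on the log2 scale within a medium, 0.299 to 0.332 between base and mucin, and 1.12 to 1.18 between base and glucose. The first principal component held 91.9% of the variance and parted the glucose libraries from the rest. The second held 4.63% and parted the mucin from the base libraries. Between libraries of the same medium, the chi-square per degree of freedom was 24.6 (mucin), 35.9 (glucose) and 39.9 (base), where counting error alone gives about 1, so no library was a copy of another.

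The question in the study's title is how the yeast responds to mucin, and the comparison that addresses it is mucin against base medium. Of the 5987 genes tested, 1474 (24.6%) changed with mucin, 757 of them higher and 717 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Most of the changes were small. The median of the raised genes was a log2 fold change of 0.69 and that of the lowered genes was -0.64, with a median SE of 0.15. A fitted difference of at least 2-fold was found for 226 of the changed genes (131 higher, 95 lower), and one of at least 4-fold for 19 (13 higher, 6 lower). No gene was at 0 in both libraries of one of these media with at least 10 reads in each library of the other. Among the 1497 genes with the highest mean log2 CPM in these media 492 changed, and among the 1497 with the lowest 166 did, with median SEs of 0.14 and 0.27.

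Single genes are given by identifier, chosen after their values were seen, because the files do not pair identifiers with names. Among changed genes with an average log2 CPM of at least 4 over all 6 libraries, glucose included, the largest rise with mucin was in orf19.1264, from 0.831 ± 0.214 CPM in base to 9.05 ± 2.93 CPM with mucin (SD, n = 2 each). Its log2 fold change was 3.41 ± 0.40 (SE; adjusted p = 0.000111), and the base value rests on 23 reads. It passes that limit only through its level with glucose. The same gene reached 59.1 ± 19.5 CPM with glucose (n = 2), and its log2 fold change of mucin against glucose was -2.72 (adjusted p = 1.25e-07). By the same limit the largest fall with mucin was in orf19.1655, from 45.9 ± 28.7 CPM to 11.7 ± 4.37 CPM (n = 2 each), a log2 fold change of -1.99 ± 0.35 (SE; adjusted p = 0.00122). Its base libraries differed widely, at 25.6 and 66.2 CPM. Its log2 fold change was -1.15 without the second base library (still past the threshold), and 2.34 ± 0.131 CPM was measured with glucose (n = 2). Some changed genes below the limit rose or fell by more, and their read counts are not given here.

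In this comparison 823 genes (418 higher, 405 lower) changed when the second base library was left out, and 434 rather than 717 were lower without the second mucin library. A fit to only the 4 libraries compared gave 1160 genes rather than 1474. A smaller count can therefore come from having fewer libraries to share the spread, and not only from the library left out. Only 14 genes (11 higher, 3 lower) passed a test against a 2-fold change instead of against no change. When libraries were scaled by their size alone, 79.2% rather than 51.4% of the calls were higher.

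Glucose against base medium compares cells given a readily fermented sugar with cells in the medium alone. Any differences in growth, growth phase and depletion of the medium after 24 h cannot be told apart from an effect of the sugar itself. Here 4873 of 5987 genes (81.4%) changed, 2580 of them higher and 2293 lower. The changes were larger than with mucin, with a median absolute log2 fold change of 1.40 (median SE 0.16) compared with 0.66. A difference of at least 2-fold was found for 3304 genes (1741 higher, 1563 lower), and of at least 16-fold for 295 genes (50 higher, 245 lower). The 245 genes that fell at least 16-fold had held 50.6% ± 1.22 of all reads in base medium and held 2.57% ± 0.283 with glucose (SD, n = 2 each). With mucin they held 46.7% ± 1.13 (n = 2). The 50 genes that rose at least 16-fold held 0.0530% ± 0.000606 of the reads in base, 0.0869% ± 0.00370 with mucin and 4.27% ± 0.209 with glucose (n = 2 each). These genes were selected by the same glucose and base libraries, so their shares in those media describe the size of the shift and are not an independent test of it.

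**Figure D2:**
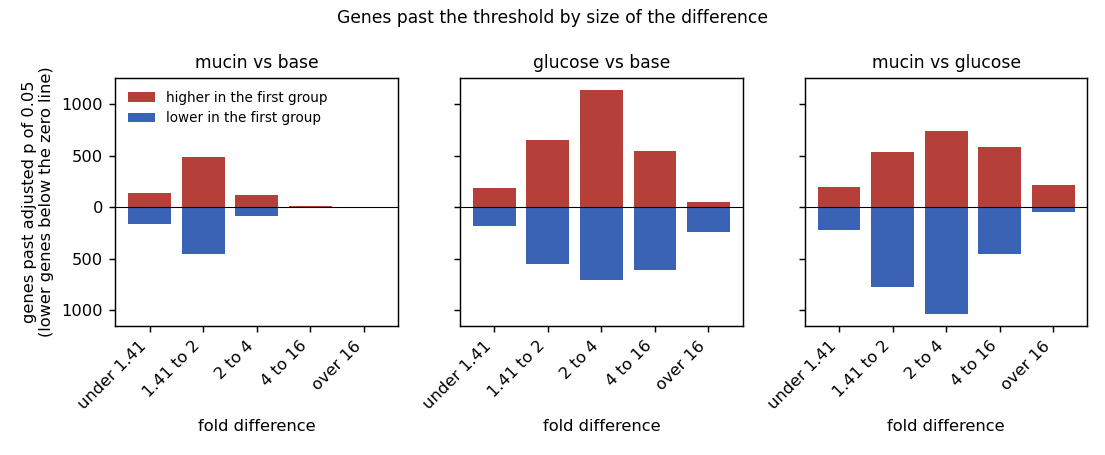
Number of genes past an adjusted p of 0.05 in each comparison (vertical axis), by size of the fitted fold difference (horizontal axis); bars above the zero line are genes higher in the first-named medium and bars below it are genes lower. With mucin against base 19 genes reach 4-fold, and with glucose against base 1455 do.

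The balance of rises and falls with glucose differed with expression level. Under TMM scaling 899 of the 1497 genes with the highest mean log2 CPM over both media fell and 431 rose, and 327 of the 1497 with the lowest fell and 770 rose. Under library-size scaling rises outnumbered falls in both classes, with 501 falls and 825 rises in the highest and 143 falls and 1178 rises in the lowest. Upper-quartile scaling gave 748 and 555, and 233 and 942. The median log2 fold changes of the highest and lowest classes were -0.80 and 0.68 with TMM, 0.57 and 2.04 with library size, and -0.33 and 1.14 with the upper quartile. Among changed genes with an average log2 CPM of at least 4, the largest rise with glucose was in orf19.1691. It had 6 and 0 reads in the base libraries and 2211 ± 3.04 CPM with glucose (SD, n = 2). The ratio of pooled reads per pooled TMM-scaled library size was 10135 (95% counting interval 4656 to 27617, which leaves out the spread between libraries). The fitted log2 fold change was 13.27, and 12.24 without the second base library. Without the first it was 18.55, a fitted value against 0 reads that is no bound. This gene had 2.30 ± 1.39 CPM with mucin (n = 2), which was above base by 3.31 ± 0.69 on the log2 scale (SE; adjusted p = 0.00333). That value was 2.29 without the second base library and 8.60, again no bound, without the first. The mucin level rests on 19 and 39 reads, against 73779 and 76463 with glucose. A small share of glucose reads mixed into the mucin libraries is not excluded for this gene. By that limit the largest fall was in orf19.5975. It had 472 ± 120 CPM in base (n = 2) and 1 and 2 reads in the glucose libraries. By the same ratio of pooled reads this was 10762 times lower (95% counting interval 3682 to 52191). With mucin it had 250 ± 63.5 CPM (n = 2), a log2 fold change against base of -0.92 ± 0.18 (SE; adjusted p = 0.00230).

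The direction given to the smaller glucose effects depends on the scaling, which moves all genes of a library alike. The TMM factors were 0.693 and 0.707 for base, 0.762 and 0.823 for mucin, and 1.71 and 1.90 for glucose. Scaling by library size alone moved the median log2 fold change of all genes from 0.13 to 1.5 and the higher share of calls from 52.9% to 81.5%, and upper-quartile scaling moved them to 0.60 and 65.2%. Because that shift is upward for every gene, small falls had to turn and rises could not, so the counts under this scaling show only how large a fall had to be to stay a fall under both scalings. Under library-size scaling all 245 genes that fell at least 16-fold and 847 of the 855 that fell at least 4-fold were still called lower. Of all 2293 lowered genes 988 were, and 716 were called higher.

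Mucin against glucose compares the 2 supplements directly. Of 5987 genes, 4823 (80.6%) differed, with 2282 higher and 2541 lower with mucin. At least 2-fold differences were found for 3089 genes (1545 higher, 1544 lower with mucin), with a median absolute log2 fold change of 1.28 over all changed genes (median SE 0.16). Genes at least 16-fold higher with mucin numbered 220 and genes at least 16-fold lower numbered 45. Of the 3304 genes that glucose changed at least 2-fold from base, 2763 also differed at least 2-fold between mucin and glucose on the same side of the glucose value. Both comparisons use the same glucose libraries, so part of this overlap may come from them. With library size as the only scaling, 19.9% rather than 47.3% of the calls were higher with mucin.

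Read together, the comparisons place mucin relative to both other media. Of the 1474 genes changed by mucin, 1251 also differed between mucin and glucose, compared with 80.6% of all tested genes. In 420 genes mucin lay above base and below glucose, with median log2 fold changes of 0.72 against base and -0.98 against glucose. In 371 genes it lay below base and above glucose, with medians of -0.62 and 1.54. A further 225 genes were higher with mucin than in both other media, with medians of 0.61 against base and 1.49 against glucose, and 36 of them were at least 2-fold above both. Another 235 genes were lower with mucin than in both other media, 27 of them at least 2-fold below both. Both tests behind these groups and behind the 1251 genes use the same 2 mucin libraries. A deviation common to those libraries could place a gene above or below both other media. Without the second base library these groups held 263, 230, 100 and 130 genes in the order given, and library-size scaling gave 966, 108, 209 and 173. The group between a higher base and a lower glucose value held 203 genes without the first and 227 without the second mucin library. The group below both held 151 and 150 genes without the first and second glucose library and 140 without the second mucin library.

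**Figure D3:**
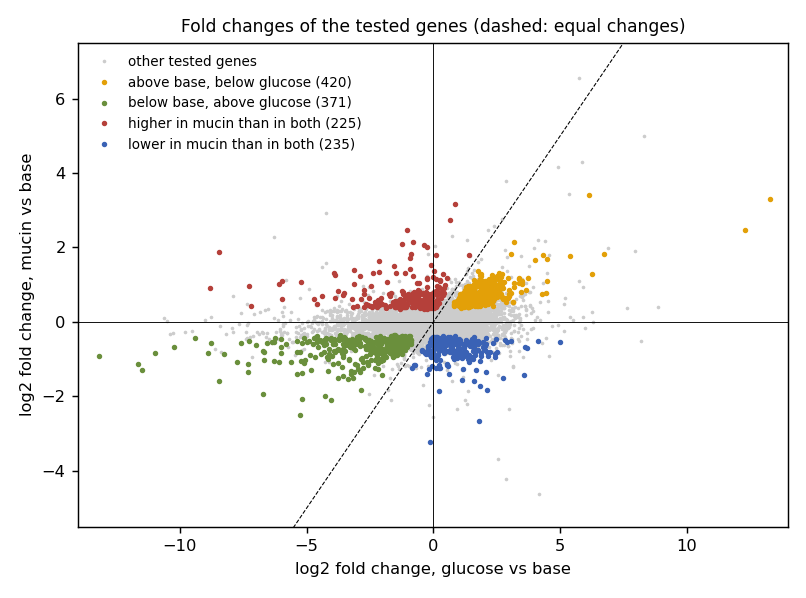
Log2 fold change with glucose against base (horizontal axis) and with mucin against base (vertical axis) of 5987 tested genes, coloured by the position of mucin where it differed from both other media (adjusted p below 0.05 in both tests). By definition the 420 and 371 genes with mucin between base and glucose lie between the horizontal axis and the dashed line of equal changes. The 420 are in the upper right, with median log2 fold changes of 0.72 with mucin and 1.74 with glucose. The 371 are in the lower left, with medians of -0.62 and -2.28.

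Genes changed by both supplements tended to move the same way. Among the genes past the threshold against base in both comparisons, 526 rose with both, 471 fell with both, 144 rose with mucin and fell with glucose, and 137 did the reverse. Independent lists of these lengths would share 326, 275, 290 and 309 genes, respectively. At a difference of at least 2-fold in both, 150 genes moved the same way and 30 in opposite ways. The 2 comparisons share the base libraries. Simulations that drew all groups, base included, from the pooled base counts gave 0.04 same-direction calls on average (at most 1 in 50 simulations). They do not carry the deviations of the real base libraries. Neither reference value accounts for both the shared libraries and the effects, so the excess is not a measure of a shared effect. Across genes, the log2 fold changes had a Pearson correlation of 0.31, compared with 0.49 in the simulations, where all variation is noise. Their covariance was 0.333, compared with 0.0222 simulated. The base group has 2 libraries and could not be split with 2 libraries on each side, so part of the excess may come from the shared controls. Without the second base library 596 genes moved the same way and 143 in opposite ways, and the covariance was 0.517. Without the second mucin library 182 moved in opposite ways, and without the first the correlation was 0.20.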

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

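The test in this part was chosen only after the result was seen. Alignments that fit more than 1 place in the reference are listed apart from the genes and were used in no comparison. Their share of the listed reads was 0.966% and 0.948% in the base libraries, 1.10% and 1.08% in the mucin libraries, and 1.88% and 1.91% in the glucose libraries, so all 4 supplemented libraries lay above both base libraries.

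The tables argue against a difference in counted depth between groups as the source of the higher glucose share. Each glucose library had a library of another medium at nearly its depth. The first glucose library (17531368 reads in genes, share 1.88%) differed by 0.343% in depth from the first mucin library (share 1.10%), and the second (20237883 reads, share 1.91%) differed by 0.434% from the second base library (share 0.948%). Depth here means reads in genes. The rows for reads assigned to no gene are 0 for a reason not given, so the full depth and the share of all reads are unknown. A higher output of genes with near-identical copies under glucose, or a different remainder of ribosomal RNA, may give such a share. Neither was tested, since the identifiers could be tied to no sequence here.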

How the results depend on the processing

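The choices below were fixed before the data were examined, except thinning and the settings for the position of mucin and for the split by expression level. No paired analysis was possible because the labels carry no replicate numbers that groups share. The planned gene list tests and their alternatives were not run, since no identifier had a symbol. In mucin against base, library-size scaling gave 1319 higher and 347 lower genes, and a test against a 2-fold change gave 14 genes (11 higher, 3 lower). In glucose against base these settings gave 4365 higher and 988 lower, and 2706 genes (1353 higher, 1353 lower). In mucin against glucose they gave 1043 higher and 4197 lower, and 2405 genes (1270 higher, 1135 lower). Library size alone leaves the composition of the libraries uncorrected, which by construction shifts all genes of a library alike. Leaving out 1 library gave 823 to 1169 changed genes in mucin against base (418 to 619 higher, 405 to 569 lower), the lowest without the second base library. The count of lower genes was 434 without the second mucin library. Same-direction overlap with glucose ranged from 596 to 812 genes and opposite-direction overlap from 143 to 230 (182 without the second mucin library), and with a 2-fold threshold they were 150 and 30. The covariance ranged from 0.287 to 0.517 and the correlation from 0.20 to 0.37. Genes above both other media ranged from 100 to 183, genes below both from 130 to 215, genes between base and a higher glucose value from 263 to 342, and genes between base and a lower glucose value from 203 (without the first mucin library) to 310. With library size alone these last groups held 966 and 108 genes. Genes below both numbered 151 and 150 without the first and second glucose library and 140 without the second mucin library, and genes between base and a lower glucose value 227 without the latter. For the counts of changed genes, DESeq2 size factors, upper-quartile scaling, DESeq2, limma-voom, both filters, fits to only the 4 libraries compared, robust and legacy fits, removal of the 20 most abundant genes and thinning stayed within 1.5 times. DESeq2 called 1412 genes in mucin against base, of which 1332 were shared in direction. Fold changes of the 4 identifiers kept their sign under each setting that gave a value, and 3 of them (orf19.1655, orf19.1691 and orf19.5975, in mucin against base) did not pass the test against a 2-fold change. The share of reads in the most abundant genes kept the order base, mucin, glucose with 10 genes (26.0%, 22.7% and 11.7%) and with 50 genes. Depth limits the genes of lowest expression, where the SE was largest.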

Other observations

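The tests in this part, except the removal of the 20 most abundant genes and library-size scaling, were chosen only after the patterns were seen. The number of genes changed by mucin is large for a small shift: 1474 genes, at a median absolute log2 fold change of 0.66. The mucin libraries were shallower (15574171 and 17591751 reads) than the base libraries (19108512 and 20150432). The tables argue against this difference in counted depth as the source, because 1422 genes passed after all 6 libraries were thinned to the smallest total. The fit already scales for library size, so a large drop was unlikely from the start and the test is weak. An influence of a few abundant genes stays open. Leaving out the 20 most abundant genes gave 1469 genes, but it moved the count of no comparison by more than 0.339%, so it decides nothing, whereas scaling by library size alone gave 1319 higher and 347 lower genes. Also open is variation between cultures that has nothing to do with mucin, since each medium has 2 libraries and the labels name no separate cultures or batches. A response to mucin, the difference the design names, is among the open explanations and has no further test here.

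A hypothesis is that mucin moved part of the transcriptome a short way along the path that glucose takes, which a small amount of usable sugar in the mucin preparation could do. The slope of the mucin effect on the glucose effect across genes was 0.0794. Noise of single base libraries is argued against as the sole source. The covariance of log2 CPM differences was 0.277 and 0.258 when a different base library served each comparison. It was 0.303 by the same measure with the base libraries shared, and 0.0222 for fitted fold changes in simulations of unchanged groups. A deviation common to both base libraries would remain in these values and is not excluded. Reads of glucose libraries mixed into mucin libraries are argued against as well. The 16 genes at least 100 times higher with glucose than in base allow such a share of at most 1.49% at their 75th percentile, while the 526 genes raised by both supplements would need 9.24% at their lower quartile. Slower depletion of the medium, another growth phase and other nutrients in mucin were not tested and stay open beside sugar.

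The 225 genes highest and the 235 genes lowest with mucin lie off that path. Of the 36 that were at least 2-fold above both other media, 26 also differed between glucose and base, and of the 27 at least 2-fold below both, 16 did. Over all tested genes 81.4% did. The selection leaves out the 420 and 371 genes with mucin between base and glucose, all of which differed between glucose and base. A lower share is therefore built into the selection, and these counts cannot decide whether there is a link with the glucose response. Genes with 0 reads in both libraries of 1 medium and at least 10 in each library of another were few. That rule leaves out steep changes with any read at the low end, such as orf19.5975 (1 and 2 reads with glucose). Between glucose and base, 295 genes differed at least 16-fold. With at least 10 reads in each library of one medium and 0 in both of the other, 3 genes were seen only in glucose and 4 only in base when those media were set side by side. For mucin and glucose the numbers were 4 seen only in mucin and 4 seen only in glucose.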
